A study of Mus musculus with 12 samples.

How the data were processed

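Hepatic microRNA was measured on 2-colour Exiqon miRCURY arrays, whose capture probes contain locked nucleic acid bases that bind short RNAs tightly. Each of 12 arrays carried total RNA from the median liver lobe of 1 male B6C3F1 mouse in the Hy5 (red) channel, and the same purchased reference, pooled from 10 mouse tissues, in the Hy3 (green) channel, per the labels. The labels give 6 mice dosed with corn oil vehicle and 6 dosed with 150 mg/kg benzo(a)pyrene (BaP), all sampled 4 h after the last of 3 daily doses. Samples taken at 24 h, which the series description also names, were not analysed here. Replicates were numbered within each group and the numbers pair no animals.

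The deposited scanner files hold spot and background brightness as intensity values on a linear scale, quantified with Agilent Feature Extraction 9.5.3.1 per the submitters' processing notes. They also hold a log10 ratio of red over green, which the scanner software computed from background-subtracted, lowess dye-normalized signals, per the file headers. The authors' deposited value table of the same arrays is on a log2 scale: set against the ratios computed here over 63 tested probes, its columns had slopes of -1.02 to -0.943 and correlations across probes of -0.994 to -0.970. It therefore runs as reference over liver, the opposite direction to that used here, and its centring is not given in the sources used here. Its column medians were -0.0061 for vehicle 1, -0.020 for vehicle 2, -0.020 for vehicle 3, -0.026 for vehicle 4, -0.048 for vehicle 5 and -0.040 for vehicle 6. In the BaP group they were -0.00034 for BaP 1, -0.092 for BaP 2, -0.043 for BaP 3, -0.044 for BaP 4, -0.012 for BaP 5 and -0.036 for BaP 6. The table lists values for 248 of 2001 probes. Of these, 229 carry a mouse name alone and 19 are controls or U6 probes, while the 366 mouse probes shared with another species have none, so the table served only as an alternative.

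Mean spot signals were corrected with normexp against the median local background (offset 50). Log2 ratios of liver over reference were normalized within each array by loess, with control and unnamed spots at weight 0, in limma 3.58.1 (R 4.3.3, statmod 1.5.0). Replicate spots, most often 4 per probe, were averaged. Spots with an outlier mark were left out where the probe kept an unmarked spot on that array, because the marks fell often on very bright spots. Saturated spots were kept. The scanner's mark for signals well above background was set for every spot and separated nothing, so the fallback written beforehand was used: a probe was detected on an array when its median net liver signal exceeded the median plus 2 SD of the negative controls. The SD was a robust one, from the median absolute deviation, since 1 of the 28 negative control spots was extremely bright on 1 array. The robust SD and the treatment of marked spots were chosen after the values were seen but before any comparison of groups.

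Of 595 probes with a mouse name, the 218 detected on at least 6 of 12 arrays were tested. Names are those of the array design. No genome build applies to the files, so no coordinates are given. Groups were compared with limma (lmFit, eBayes, two-sided) and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Differences are BaP minus vehicle on the normexp scale, where the offset of 50 understates changes of dim probes. In 20 simulated data sets on these 218 probes, the comparison of BaP with vehicle recovered 57.0% of changes of 0.25 log2 units, 89.5% of changes of 0.50 and 98.0% of changes of 1. In each set 40 probes were changed, 10 of each of 4 sizes, and the adjustment grows stricter when fewer change. With 4 probes of 1 size changed per set, a test added after seeing the data, 25.0% of changes of 0.25 were recovered. When nothing was changed, 1 of 20 simulated data sets gave any call. The simulation had no scan-day effect, no correlation between probes and no outlying array, so its rates need not hold for these data.

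Of 13 miRNA lists fixed in advance, the 11 with at least 3 tested probes were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. Erythroid and endothelial lists had 2 tested probes each and give values only. The probes named are the 10 with the smallest p among those higher after BaP, the 10 with the smallest among those lower, whether or not they pass, and every tested list member, which makes 80 probes. A probe below the detection limit in liver on every vehicle array has only a bound. Its bound is the mean reference signal over the mean, per array, of the higher of its own liver signal and the lowest detected one, both after loess and Aquantile normalization. All livers carry the same dye, so ratios of liver to reference stay open to dye bias, which cancels between groups.

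Arrays were scanned on 4 days, each holding both groups, and each array was a slide of its own, so scan day was fitted as a block. Alternatives chosen before the data were examined were no background correction, the scanner's log ratio, median centring, Aquantile, the liver channel alone, the authors' values, 3 other probe filters, a trended robust fit, array weights, the scan-day block, other thresholds, an exact permutation test and leaving out each array. Added after seeing the data were 2 other treatments of marked spots, a normexp offset of 0, leaving out vehicle 5 and BaP 2, bright probes only (mean net liver signal above 200), a plain SD for the detection limit, the reference channel alone, and an estimated correlation in the settings where a list passed. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).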

Results

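Hepatic miRNA levels were compared between 6 mice dosed with corn oil and 6 mice dosed with 150 mg/kg BaP, a polycyclic aromatic hydrocarbon that liver enzymes activate to DNA-binding metabolites, 4 h after the last dose. The design text describes each group as 6 mice, so replicates are treated as separate animals. The arrays held 595 probes with a mouse miRNA name. Between 189 (BaP 5) and 367 (vehicle 1) of them were detected in the liver channel. The detection limit ran from -0.14 net units on BaP 1, with 304 probes detected, to 24.3 on BaP 2, with 272, and was 0.387 on vehicle 1. The median net liver signal of the 218 tested probes ranged from 52.8 units on BaP 3 to 112 units on vehicle 5. The number of arrays limits the precision of every comparison.

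Hepatocyte-enriched miRNAs lay on the liver side of the ratio to the pooled tissues, and several markers of other cells and organs on the reference side. All ratios are liver over reference, the opposite direction to the authors' deposited table. In vehicle mice, miR-122, the most abundant miRNA of hepatocytes, stood at a log2 ratio of 3.72 ± 0.17 (SD, n = 6). The ratio was 2.95 ± 0.19 for miR-193, 2.86 ± 0.15 for miR-192 and 2.59 ± 0.16 for miR-194 (SD, n = 6 each). In BaP mice, miR-122 stood at 3.80 ± 0.13 (SD, n = 6). The leukocyte miRNA miR-142-3p was at -3.42 ± 0.19 in vehicle mice and the erythroid miR-451 at -2.22 ± 0.45 (SD, n = 6 each). Among the mesenchymal markers, miR-125b-5p was at -2.77 ± 0.16 and miR-143 at -2.50 ± 0.23 (SD, n = 6 each). Other markers lay on the liver side: miR-125b-3p, of the same list, at 0.93 ± 0.12, the epithelial miR-31 at 1.03 ± 0.17 and miR-203 at 0.56 ± 0.18, and pancreatic miR-375 at 0.28 ± 0.056 (SD, n = 6 each).

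Muscle miR-1 was not detected in the liver channel of any vehicle array, and its reference signal was at least 16.9-fold higher. The corresponding bounds were at least 11.6-fold for miR-133a, 4.72-fold for miR-138, 4.49-fold for miR-128 and 3.98-fold for miR-133b. Neuronal miR-124 was detected in liver on 1 of 6 vehicle arrays and in the reference on 6, so no ratio is given for it. Not all markers of other organs were below the detection limit in the liver channel. There, miR-208a was detected on 6 of 6 vehicle arrays, at -0.83 ± 0.22, and miR-208b on 4, at -0.16 ± 0.086 (SD, n = 6 each). Both were dim, with mean net liver signals over all 12 arrays of 42.6 and 19.2 units. Cross-hybridisation was not tested for them, so their presence in liver is not shown. These levels are described without a test, since tissue and dye cannot be separated.

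**Figure D1:**
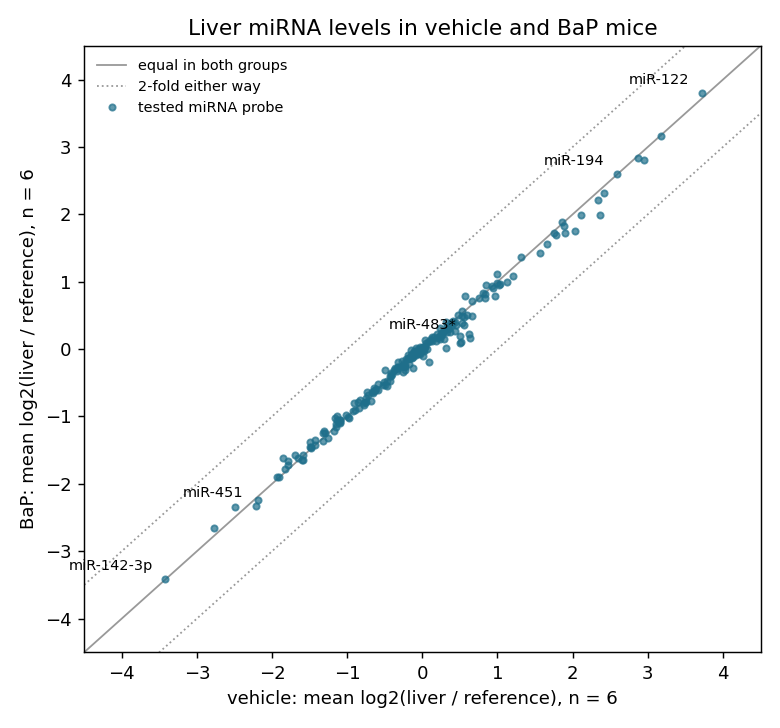
Mean log2 ratio of liver to reference for each of 218 tested miRNA probes in vehicle mice (x axis) and BaP mice (y axis), 6 arrays each. The solid line marks equal values and the dotted lines a 2-fold difference. All points lie between the dotted lines, and miR-122 lies at 3.72 in vehicle and 3.80 in BaP mice.

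The main question was which hepatic miRNAs change after BaP. No miRNA passed the threshold: limma found 0 of 218 probes at an adjusted p under 0.05, and the smallest adjusted p was 0.781. At an unadjusted p under 0.05, chance gives 10.9 probes on average. The median count over other drawn splits of the 12 samples, described below, was 6. The real groups gave 4 probes, 2 with higher and 2 with lower values after BaP. This balance moved with the processing: 4 were higher and 0 lower with the scanner's log ratio, 3 and 0 without background correction, 5 and 2 with an offset of 0, 1 and 2 in the liver channel alone, 2 and 0 in the authors' values, and 1 and 7 with array weights, while median centring gave 0. The count was 1 without BaP 2, and 2 without vehicle 1, without vehicle 4 or without BaP 3. An exact permutation test of each probe, two-sided over 462 splits, gave 0 probes after adjustment, with 3 at an unadjusted p under 0.05. The smallest p this test allows is 0.0022. A single probe among 218 could not pass with it after adjustment, so its 0 was close to fixed. The median absolute difference was 0.043 log2 units and the largest was 0.46. It belonged to miR-483*, singled out here after its value was seen, at -0.46 with all arrays and -0.038 without vehicle 5. With scan day as a block, 0 probes passed, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.309.

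The intervals give the range of change left open for each probe on the normexp scale. The offset understates changes of dim probes on that scale, so the intervals do not bound the change of such probes. For the dim probe miR-34c*, the interval ended at 0.30, while the difference was 0.44 in the scanner's log ratio. For 213 of 218 probes (97.7%), the 95% confidence interval of the change lay within 2-fold either way, and for 206 (94.5%) within 1.5-fold. The tighter bound depends on the scaling, with 171 of 218 (78.4%) within 1.5-fold under median centring, 194 (89.0%) with the scanner's log ratio and 195 (89.4%) with an offset of 0. The 5 probes whose interval reached beyond 2-fold were miR-129-3p, miR-715, miR-184, miR-483* and miR-345-5p. They were named after their values were seen. On all of these but miR-184, the array of vehicle 5 lay 2.14 to 2.65 log2 units above the other vehicle arrays. Without it their differences lay between -0.044 and 0.030, while that of miR-184 ranged from -0.50 to -0.055 as single arrays were left out. Among 63 probes with a mean net liver signal above 200, a selection made after seeing the data, 63 intervals lay within 2-fold and 60 within 1.5-fold.

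Of the probes with the smallest p and higher values after BaP, miR-34c* led with a log2 difference of 0.18 (SE 0.052, limma adjusted p = 0.781). All 6 BaP livers lay above the vehicle mean and 4 above every vehicle liver. Its within-day differences were 0.19, 0.17, 0.16 and 0.22 on scan days 1 to 4, and the blocked difference was 0.18 (adjusted p = 0.309). The probe was dim, with a mean net liver signal of 25.1 units, and its difference was 0.086 in the liver channel alone and 0.44 in the scanner's log ratio. Next came miR-805 at 0.23 (SE 0.097, limma adjusted p = 0.987), with 5 of 6 BaP livers above the vehicle mean and a range over the alternatives of 0.13 to 0.32. The p53-induced miR-34a differed by 0.15 (SE 0.068, limma adjusted p = 0.987), and 5 of 6 BaP livers lay above every vehicle liver. Its within-day differences were 0.097, 0.11, 0.16 and 0.038, with 0.11 under the block. Over the alternatives it ranged from 0.093 without vehicle 5 and BaP 2 to 0.30 in the scanner's log ratio, with 0.25 with an offset of 0. The remaining 7 of these 10 were miR-710, miR-711, let-7e, miR-99b, miR-706, miR-200a and miR-503, with differences of 0.093 to 0.23. In the liver channel alone miR-711 was at -0.029 and miR-503 at -0.053, with miR-710 at 0.0089, miR-706 at 0.012 and miR-200a at 0.062. The highest values of these 7 over the alternatives lay between 0.20 for miR-503 and 0.36 for miR-710 and miR-200a.

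Among probes with lower values after BaP, miR-31* led with a difference of -0.17 (SE 0.068, limma adjusted p = 0.987), and all 6 BaP livers lay below the vehicle mean. In the liver channel alone its difference was -0.013, and with an offset of 0 it was -0.35. For the hepatocyte-enriched miR-455 the difference was -0.20 (SE 0.089, limma adjusted p = 0.987), and 5 of 6 BaP livers lay below every vehicle liver. Its within-day differences were -0.21, -0.15, -0.22 and -0.12, and the blocked difference was -0.18 (adjusted p = 0.569), with -0.084 under median centring. The other 8 were miR-712, miR-487b, miR-291a-3p, miR-21, miR-365, miR-320, miR-489 and miR-877*, with differences of -0.30 to -0.085. The difference of miR-877* rests on vehicle 5, whose ratio was 1.59 against 0.061 for the mean of the other 5 vehicle arrays, and was -0.046 without that array. That of miR-21 was -0.076 without BaP 2.

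**Figure D2:**
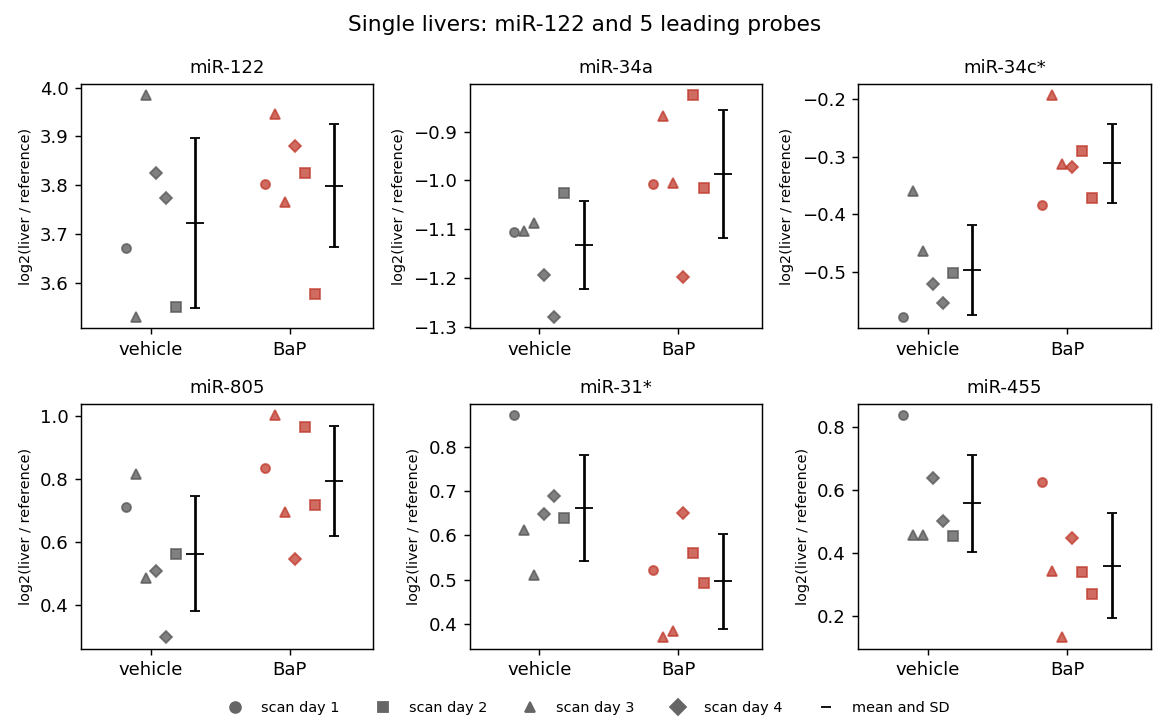
Log2 ratio of liver to reference in each of 12 livers for miR-122 and 5 leading probes, by group, with marker shape for scan day and bars for mean and SD (n = 6). The vertical axes have different ranges and do not start at 0. For miR-34c*, 4 of 6 BaP livers lie above every vehicle liver, and for miR-34a 5 of 6, while neither probe passed the adjusted threshold.

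The lists asked whether groups of miRNAs shifted together. None of 11 tested lists passed (camera, smallest adjusted p = 0.310). With an estimated correlation the smallest adjusted p was 0.847, and with fry it was 0.926. No member of any list passed adjusted over the list alone or over all tested probes, and 1 of 66 distinct tested members, miR-455, had an unadjusted p under 0.05. The sign of the mean difference turned under at least 1 scaling alternative for 8 of 13 lists, so means below are given as values without direction. Median centring raised the median difference over all 218 tested probes from 0.0056 to 0.081. Under it the hepatocyte-enriched mean moved from -0.053 to 0.031 and the inflammation mean from -0.078 to 0.013. Sign turns under median centring therefore go largely with a shift shared by the tested probes. Turns under other scalings are not covered by this: the lipid and glucose mean was -0.028 in the liver channel alone. Leaving out 1 array turned the sign for 31 of the 80 named probes, all of them list members and 0 of them among the 20 leading probes. It turned the sign or moved the difference by over 1.5 times for 68 of the 80, and for 9 of the 20. The 20 leading probes were chosen by their p in these data, which favours differences that keep their sign. Their count of 0 turns therefore shows little.

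Of the 8 hepatocyte-enriched probes, 0 passed, with a list mean of -0.053 (adjusted p = 0.310). Its differences ran from -0.20 for miR-455 to 0.097 for miR-802, and miR-122 differed by 0.077 (SE 0.085). The mean was 0.031 under median centring, and ranged from -0.10 to -0.011 (without vehicle 1) as single arrays were left out. By scan day it was -0.035, 0.021, -0.099 and -0.028, and -0.043 under the block. The p53 and DNA damage list, of interest because BaP metabolites damage DNA, had 10 tested probes and a mean of 0.033 (adjusted p = 0.445), with a range of 0.0024 to 0.065 over single arrays left out and -0.0052 without vehicle 5 and BaP 2. Beside miR-34a it held miR-143 at 0.15 (SE 0.20), which was -0.040 without BaP 2, miR-16 at -0.037 (SE 0.11; 0.0023 without BaP 6) and miR-34b-3p at -0.016 (SE 0.077; 0.025 without vehicle 4). Its mean by scan day was 0.099, -0.021, 0.075 and 0.0030, and 0.040 under the block. The miR-34b-5p and miR-34c probes were not detected in the liver channel of any array.

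The 6 probes related to xenobiotic metabolism had a mean of -0.019 (adjusted p = 0.777), which was 0.015 without vehicle 1, 0.0049 without BaP 3 and 0.013 without BaP 6, with miR-27b at 0.040 (SE 0.051) and miR-148a at -0.14 (SE 0.11). Without vehicle 5 miR-27b was at 0.016, and without vehicle 1 miR-148a was at -0.069. For the 9 let-7 probes, which differ by few bases and can share signal, the mean was 0.029 (adjusted p = 0.609). It was -0.031 without BaP 2, -0.012 without vehicle 2 and -0.044 without vehicle 5 and BaP 2. Among them let-7a differed by 0.087 (SE 0.12), or -0.0030 without BaP 2, and let-7b by -0.083 (SE 0.086). The 8 probes of the miR-17-92 and related clusters, which promote proliferation, had a mean of -0.015 (adjusted p = 0.777). The mean was -0.097 in the liver channel alone, where the list passed (adjusted p = 0.047, with a range over the alternatives of 0.047 to 0.997, and adjusted p = 0.992 with an estimated correlation). The list mean was 0.0083 without BaP 3, 0.0010 without BaP 4 and 0.0034 without vehicle 6, but -0.054 without BaP 5 and -0.052 without vehicle 5. For the 7 probes tied to lipid and glucose metabolism the mean was 0.061 (adjusted p = 0.387), with miR-29b at 0.11 (SE 0.099) and miR-29a at -0.017 (SE 0.091; 0.026 without BaP 6). That mean ranged from 0.024 to 0.10 as single arrays were left out, with 0.029 without vehicle 5 and 0.032 without BaP 5. It was -0.028 in the liver channel alone and 0.14 under median centring. By scan day, the xenobiotic mean was -0.031, -0.035, -0.017 and 0.0026, and -0.019 under the block. The let-7 mean was -0.0059, -0.058, 0.14 and 0.038 by day, and 0.045 under the block. Corresponding values for the miR-17-92 list were 0.023, -0.033, -0.10 and -0.0082, and -0.043. For lipid and glucose metabolism they were 0.085, 0.10, 0.027 and 0.070, and 0.065.

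The inflammation list had 4 tested probes, each with a negative difference, and a mean of -0.078 (adjusted p = 0.310, and adjusted p = 0.847 with an estimated correlation). Its widest difference was that of miR-21, induced in many injured tissues, at -0.17 (SE 0.12). The list passed without vehicle 1 (mean -0.099, adjusted p = 0.016) and without BaP 5 (mean -0.11, adjusted p = 0.039). With an estimated correlation neither call held, at an adjusted p of 0.325 and an adjusted p of 0.582. The mean was -0.039 without BaP 2 and 0.013 under median centring. Over the alternatives its adjusted p ranged from 0.016 to 0.696. By scan day the mean was 0.070, -0.10, -0.20 and -0.065, and -0.096 under the block (adjusted p = 0.059).

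Marker lists held miRNAs named as markers of other cells of the liver and of other organs. Whether they follow cell content was not tested. The 4 leukocyte probes had a mean of -0.099 (adjusted p = 0.387), with miR-150 at -0.29 (SE 0.27), or 0.016 without vehicle 5, and miR-142-3p at 0.0034 (SE 0.083; -0.047 without vehicle 5). The array of vehicle 5 carried a miR-150 ratio of 1.62, against -0.21 for the mean of the other 5 vehicle arrays. The list mean was -0.041 without vehicle 5 and -0.033 without vehicle 5 and BaP 2 (adjusted p = 0.790). The list passed in the liver channel alone (mean -0.20, adjusted p = 0.016) and with an offset of 0 (mean -0.18, adjusted p = 0.037). With an estimated correlation neither call held, at an adjusted p of 0.171 and an adjusted p of 0.145. Over the alternatives its adjusted p ranged from 0.016 to 0.790. The 8 stellate and smooth muscle probes had a mean of 0.056 (adjusted p = 0.425), with -0.022 without BaP 2 and -0.053 without both that array and vehicle 5. For the 4 biliary and other epithelial probes the mean was 0.050 (adjusted p = 0.777), with miR-200a at 0.23 (SE 0.14). Without BaP 2 the mean was -0.0016 and miR-200a was at 0.099. The 3 tested markers of other organs had a mean of 0.026 (adjusted p = 0.777), with -0.0075 without BaP 2. Erythroid miR-144 differed by -0.17 (SE 0.26) and miR-451 by -0.11 (SE 0.21). Their mean of -0.14 was 0.026 without vehicle 1 and -0.25 without BaP 5. Endothelial miR-126-3p differed by -0.052 (SE 0.084) and miR-126-5p by -0.069 (SE 0.090). Their mean of -0.061 ranged from -0.091 to -0.017 as single arrays were left out, and was 0.030 under median centring.

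By scan day, the leukocyte mean was 0.012, -0.016, -0.078 and -0.26, and -0.091 under the block. Corresponding values were 0.065, -0.036, 0.13 and 0.041 for the stellate list, and 0.059 under the block. The biliary list gave 0.072, -0.021, 0.11 and 0.031, and 0.054. For other organs the values were 0.0042, -0.023, 0.042 and 0.099, and 0.033. The erythroid mean was -0.60, 0.097, -0.34 and 0.072, and -0.18 under the block. For the endothelial pair the values were -0.072, -0.011, -0.072 and 0.024, and -0.035.

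**Figure D3:**
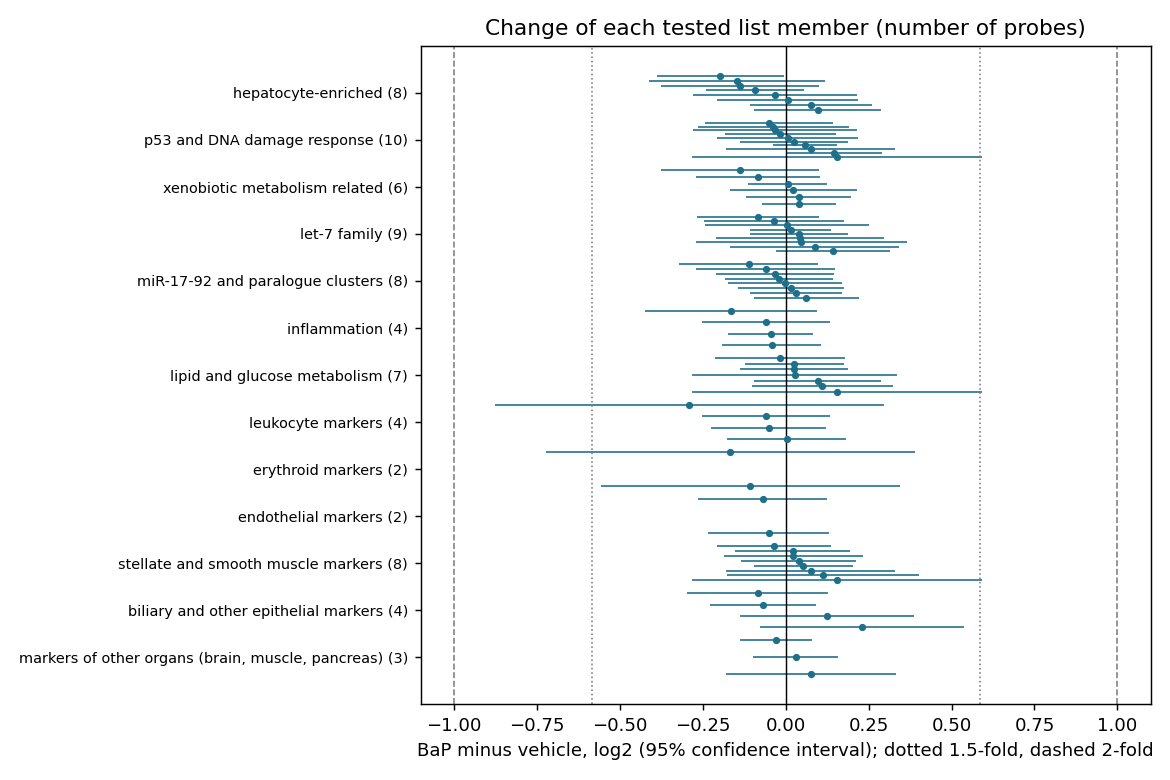
BaP minus vehicle difference (log2, x axis) with its 95% confidence interval for each tested member of the 13 lists, grouped by list with the number of probes. Dotted lines mark 1.5-fold and dashed lines 2-fold either way. All intervals shown lie within 2-fold, and that of miR-150 is the widest, from -0.88 to 0.30.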

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

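The test of leukocyte markers and all tests of miR-34a and miR-34c* were chosen after the results were seen, as were the counts of splits for probes past the adjusted threshold and for lists. Splits within scan days were added after the other counts of splits were seen. Within groups of 6, a sample was picked out when its gap to the nearest other exceeded Dixon's 95% critical share of the group's range. Of 186 groups examined over the named probes and lists, 17 had such a sample, where chance gives about 9.3.

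Vehicle 5 accounted for 7 of the 17. It lay high for miR-150 (1.62 against -0.21 for the mean of the other 5, gap 0.845 of the range), miR-877* (1.59 against 0.061, gap 0.795), miR-711 (0.16 against 0.0024, gap 0.745) and the leukocyte list (gap 0.752). It lay low for miR-320 (gap 0.843), miR-106b (gap 0.733) and the miR-17-92 list (gap 0.666). BaP 2 lay high for let-7d (0.041 against -0.82, gap 0.732), miR-200a (gap 0.699), miR-145 (gap 0.646) and the stellate list (gap 0.682). Vehicle 1 lay high for miR-365 (gap 0.652) and miR-802 (gap 0.631). Vehicle 2 lay low for miR-16 (gap 0.665) and miR-15a (gap 0.632). BaP 1 lay high for miR-712 (gap 0.658) and BaP 5 for miR-93 (gap 0.726).

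On vehicle 5, 7 mouse probes stood more than 1 log2 unit above the other vehicle arrays in the liver channel, led by miR-483* (5.02-fold) and miR-345-5p (4.36-fold), while their reference signal moved by -0.26 to 0.17. On 100% of these probes all 4 spots were raised, which argues against a defect confined to single spots. The probes were picked by their excess on this same array, which favours that outcome. Where their spots lie on the slide was not examined, so a wider local defect stays open. Leukocytes in the sample are argued against, because miR-142-3p, miR-142-5p and miR-223 had a median difference of -0.15 while miR-150 stood 1.84 higher. Labelling or cross-hybridisation of RNA other than mouse miRNA stays open: 9.23% of detected capture probes with no mouse name were raised, against 3.20% of mouse probes. Both shares are of probes detected on vehicle 5 itself. A probe near the detection limit elsewhere enters the count because it is raised there, so the 2 shares cannot decide the question. The design names no biological difference for this mouse, and none besides leukocytes was tested.

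Both miR-34a and miR-34c* stood among the leading probes higher after BaP without passing. The reference RNA is the same on every array, so a group difference there is technical. For miR-34c* the reference channel differed by -0.098 (95% interval -0.25 to 0.056), and for miR-34a by 0.019 (95% interval -0.14 to 0.18). Both intervals include 0 and a value of minus 50% of the ratio change, so a share from the reference channel cannot be told apart from a change in liver. A response of the p53 list as a whole stays open too, at a camera adjusted p of 0.445, although its mean of 0.033 became -0.0052 without vehicle 5 and BaP 2. Of the other miR-34 probes, miR-34b-3p was detected in liver on 12 arrays and differed by -0.016 (95% interval -0.18 to 0.15). The miR-34b-5p and miR-34c probes were detected in liver on no array. A BaP effect on single members of the miR-34 family may remain, untested beyond this.

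Chance cannot be excluded for the counts at an unadjusted p under 0.05. Of 100 splits of the 12 samples, the real one included, 67 gave at least the 4 probes and the highest other gave 53. For the 1 list, 94 splits gave as many and the highest other gave 5. These splits mix the scan days, which the real groups share. Of 108 splits that keep the group sizes of each day, 100 were drawn, the real one included, and fitted with scan day as a block: 56 gave at least the real 6 probes (47 in the highest other) and 65 at least the real 2 lists (5 in the highest other). Past an adjusted p of 0.05 the real counts were 0 probes and 0 lists, which all 100 splits reach by construction, so those comparisons say nothing about chance. The highest other split gave 11 probes and 4 lists. The split with 53 probes put all arrays of scan days 1 and 4 plus BaP 2 on 1 side. That split largely follows scan day. Both it and the within-day split with 47 are the most extreme of 100 and were picked after the counts were seen. Whether such counts need a structure of the samples was not tested. With scan day as a block 0 probes passed between groups.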

How the results depend on the processing

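Under all 31 alternatives, the exact permutation test among them, 0 probes passed an adjusted p of 0.05, and the smallest adjusted p was 0.241, with an offset of 0. Aquantile leaves the log ratios as they are, so its count was fixed and shows nothing. The exact permutation test allows no p below 0.0022, so its 0 was close to fixed and shows little. The count was 0 at an adjusted p of 0.2 and 4 at an unadjusted p of 0.05, which ranged from 0 with median centring to 13 without the filter on dim probes. Those 13 were among 595 probes. Leaving out each array gave 0 probes past the threshold throughout, 212 to 217 intervals within 2-fold and 201 to 213 within 1.5-fold. Against 213 and 206 of 218, intervals within 2-fold and 1.5-fold numbered 61 and 57 in the authors' values (63 probes), 590 and 579 without the filter (595), 492 and 466 over all capture probes (512), and 63 and 60 for bright probes (63), where the number tested differs. With 218 tested they numbered 215 and 171 under median centring, 210 and 194 with the scanner's log ratio and 210 and 195 with an offset of 0. Lists past the threshold numbered 0, but 2 in the liver channel alone (leukocyte and miR-17-92) and 1 with an offset of 0 (leukocyte). They ranged from 0 to 1 when arrays were left out, the 1 being inflammation without vehicle 1 (adjusted p = 0.016) or BaP 5 (adjusted p = 0.039). With an estimated correlation in these 4 settings, chosen after seeing the data, 0 lists passed, with smallest adjusted p values of 0.171 in the liver channel alone, 0.145 with an offset of 0, 0.325 without vehicle 1 and 0.582 without BaP 5. The vehicle miR-122 ratio was 3.72, and 4.12 with an offset of 0. The cause of these moves was not tested. Filters, Aquantile and the trended robust fit cannot change a probe's difference. Under the other settings, 4 values of the 20 leading probes had the opposite sign: 2 in the liver channel alone, 1 under median centring and 1 without vehicle 5 and BaP 2. Fits with other flag rules, an offset of 0, without vehicle 5 and BaP 2, on bright probes or with a plain SD were added after seeing the data. The authors' values left too few list members to test any list. No paired analysis was possible because the labels pair no animals. Low signal limits the dim probes, whose changes the offset compresses.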

Other observations

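More probes differed between scan days than between groups. With group in the model, limma found 20 of 218 probes that differed between the 4 scan days at an adjusted p under 0.05, and 57 at an unadjusted p under 0.05, against 0 and 6 between groups with scan day as a block. This comparison was chosen after the data were seen. It sets a joint test over 4 days against a test of 1 difference, so the counts come from unlike tests. Correlations across the tested probes had a median of 0.984 for 13 pairs of arrays of the same day and 0.975 for 53 pairs of different days. Probes are not independent replicates.

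The first principal component held 38.4% of the variance and placed vehicle 5 at 5.80, with the other 11 arrays between -1.22 and 0.11. The second held 22.1% and placed BaP 2 at -3.23. Array weights were lowest for BaP 1 (0.417), BaP 2 (0.421) and vehicle 5 (0.427).

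The reference channel alone, which holds the same RNA on every array, gave 0 of 218 probes at an adjusted p under 0.05 between groups and 3 at an unadjusted p under 0.05. The ratio gave 0 and 4.

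Of 10 leading probes higher after BaP, 8 were higher on each of the 4 scan days, and of 10 leading lower probes 6 were lower on each. These probes were chosen by their p, which favours days that point the same way. Over all 218 tested probes, 20 were higher and 18 lower on every day, where chance gives 6.25% in each direction.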
